A study of Mus musculus with 16 samples.

How the data were processed

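Ear skin of 16 B6 mice was profiled by RNA sequencing in 4 groups of 4: normal or high-fat diet, each with and without PMA. Per the labels' protocols, RNA was extracted with TRIzol and a spin-column kit and ERCC spike-in RNA was added. Of the RNA 2 ng were turned into cDNA by SMART-Seq2 and into libraries with Nextera XT, and paired-end reads of 151 bases were taken on an Illumina instrument. SMART-Seq2 amplifies polyadenylated RNA by PCR and carries neither strand information nor molecular identifiers. The authors deposited 1 table of whole-number counts per gene, with 1 column per library and a gene length, and these raw counts were used as deposited. STAR 2.3, featureCounts 1.5 and the builds GRCm38 and mm10 are named per the submitters' processing notes. The role and settings of each tool, the strand setting and the annotation release are not given in the sources used here. The treatment protocol reads alike for every sample, so groups were taken from the diet and treatment labels, and whether untreated ears received the solvent of PMA is not given in the sources used here. The table had 0 ERCC entries and 0 entries that name no gene, and every library column matched 1 sample.

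Library totals lay between 7739487 and 15571389 counts, so that a gene at 1 CPM had between about 8 and 16 counts in a library and lower levels rest on few counts. Intervals and SDs do not separate PCR duplicates from molecules.

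Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 17604 of 48440, and 18858 genes had 0 counts in every library. Libraries were scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood (robust, R 4.3.3) in 1 fit of 4 group means over all 16 libraries, without covariates. The 5 contrasts were the diet effect in PMA-treated and in untreated skin, the PMA effect in ND and in HFD mice, and their interaction. Genes were called below a Benjamini-Hochberg-adjusted p of 0.05 over all genes tested. SEs were computed as the absolute log2 fold change divided by the square root of F. CPM per library used the TMM-scaled totals, and log2 CPM a prior count of 2. Where a symbol had several gene IDs (113 symbols), the one with most counts was used.

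The groups, contrasts, tests, gene lists, rule for named genes and other settings to be tried were chosen before the data were examined. Of 32 lists, 31 were tested and 1 of sex-linked genes served as a check of the samples. Each list was compared with all other genes by camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided and BH-adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from the data, and fry was run as a self-contained test of whether a list's genes move, on balance, 1 way. Members were counted as called over all genes and as called when adjusted over the list alone.

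For each comparison the named genes were those with adjusted p below 0.05, a mean CPM of at least 5 over the 8 libraries compared (16 for the interaction) and groups whose 4 values did not overlap, taking the 8 with the largest increase and the 8 with the largest decrease. Symbols of predicted models, immunoglobulin and T cell receptor segments, and rDNA and mitochondrial genes were skipped. Up to 4 called members of each list with the largest absolute log2 fold change and mean CPM of at least 5 were added, or, without any, the 2 with the smallest p as values only. The text gives a part of them, and a gene outside the rule is said to be so. Genes with 1 to 3 counts or fewer in a group have CPM values only. Positions are those of GENCODE M21 on GRCm38, matched by gene ID.

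Of 165 genes followed, 28 share exon bases with another annotated gene, 23 of them on the opposite strand only, and without strand their reads cannot be assigned with certainty. These include Ccna2, Col3a1, Cry2, Csf1r, Degs2, Far2, Fn1, Il4ra, Junb, Krt32, Krt6a, Krt6b, Nr1d1, Plk1, Slpi, Tdh, Tef, Top2a and Ube2c. Members of near-identical families (Sprr1 and Sprr2, Lce, Krt6a and Krt6b, Serpina3, Cd209, Scd) and Flg, which has several gene IDs, are uncertain for the same reason.

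The procedure was tested on simulated data, with counts drawn for the 17604 genes in 5 simulations. For the diet effect in PMA-treated skin it recovered 10.4% of genes changed 1.5-fold, 40.1% changed 2-fold and 76.3% changed 4-fold, with 5.1% false calls. For the PMA effect in HFD mice these were 12.2%, 39.2%, 76.9% and 4.7%, and for the interaction 2.67%, 14.1%, 63.6% and 7.1%. Camera found the changed list in 5 of 5 simulations and called 0 of 150 unchanged lists. Genes were drawn independently of each other there, so this cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.

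Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter or a stricter one (CPM of at least 5 in 4 libraries), the replicate number as a block. Others were the library ID series as a covariate, a contrast of libraries of 1 series, and the 37 mitochondrial genes left out. Limma voom with quality weights, a fit of the 8 libraries compared, and each library left out in turn were run too. A contrast of 1 series left out the HFD_cont libraries of the other series, and its fit kept the remaining groups of both series. Scaling to ERCC was not run, as the table had no ERCC entries. Further settings were added after seeing the data: the mean of the hair list as a covariate, the 4 libraries with a hair list mean above 4 left out, and HFD_PMA replicate 1 and ND_PMA replicate 2 left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.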

Results

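Gene expression was measured by RNA sequencing in the ear skin of B6 mice that had received a normal diet (ND) or a high-fat diet (HFD, 8 weeks). Ears were left untreated or were taken 24 h after 200 ng per ear of PMA, a phorbol ester that activates protein kinase C and is used to provoke skin inflammation and epidermal thickening. The 16 libraries fell into 4 groups of 4 mice each: untreated ND, untreated HFD, PMA-treated ND and PMA-treated HFD, written ND_cont, HFD_cont, ND_PMA and HFD_PMA where single replicates are named. Library totals ran from 7739487 to 15571389 counts. Group means (SD, n = 4) were 9228853 ± 1261533 counts in untreated ND, 10983406 ± 2858265 in untreated HFD, 12982170 ± 2443168 in PMA-treated ND and 11204727 ± 2362657 in PMA-treated HFD skin. Of 48440 listed genes, 17604 had enough counts to be tested. Pearson correlations of log2 CPM between libraries of 1 group ran from 0.926 to 0.959. No 2 libraries of a group agreed within sampling noise, since their counts differed with a chi-square per degree of freedom of at least 9.68. Levels are given as mean CPM ± SD over the 4 libraries of a group, and log2 fold changes with their SE. The labels give library IDs in 2 series: all 4 untreated ND libraries and HFD_cont replicate 1 begin with RHS and the other 11 begin with RHP. What this prefix stands for is not given in the sources used here. Numbers of called genes computed within or adjusted for it stand beside the comparisons it touches, and numbers of lists follow with the other settings.

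The first comparison asked how the diet altered skin that had been exposed to PMA. In PMA-treated ears of HFD mice 5 of 15 interleukin-1 (IL-1) family genes and 3 of 22 cornified envelope genes were higher, and 6 of 14 fibroblast matrix genes and 3 of 10 type 2 immunity genes lower, than in those of ND mice. Il1f6, which encodes the keratinocyte cytokine IL-36 alpha (chromosome 2, 24215418 to 24225702, GRCm38), stood at 27.5 ± 3.08 CPM in ND and 67.3 ± 10.1 CPM in HFD mice (log2 fold change 1.29 ± 0.23 SE, edgeR BH-adjusted p = 0.0068). Lcn2, encoding an iron-sequestering antimicrobial protein of neutrophils and keratinocytes, rose from 18.1 ± 7.82 to 64.4 ± 18.9 CPM (log2 fold change 1.83 ± 0.31, edgeR BH-adjusted p = 0.00398). It was the 1 called member of 9 neutrophil genes, also when adjusted over the list alone. The neutrophil list did not pass camera (BH-adjusted p = 0.215, and 0.613 with an estimated correlation). The type I collagen gene Col1a1 (chromosome 11, 94936224 to 94953042, 52 exons) fell from 1886 ± 615 to 985 ± 338 CPM (log2 fold change -0.94 ± 0.23, edgeR BH-adjusted p = 0.0345). Ccl24, a chemokine that attracts eosinophils (chromosome 5, 135569937 to 135573049), fell from 12.3 ± 4.70 to 2.79 ± 0.508 CPM (log2 fold change -2.14 ± 0.35, edgeR BH-adjusted p = 0.00378).

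Of 15 measured genes of the list of IL-1 family and inflammatory cytokines, 5 rose with the diet in PMA-treated skin and none fell, and 9 rose when adjusted over the list alone. Beside Il1f6 these included the IL-1 receptor antagonist gene Il1rn (188 ± 11.1 to 348 ± 96.5 CPM), Il18 (25.7 ± 5.68 to 43.9 ± 5.04 CPM) and Il1f9, which encodes IL-36 gamma (149 ± 17.6 to 240.1 ± 25.2 CPM). The list was higher than other genes by limma's camera test (BH-adjusted p = 1.66e-12, and adjusted p = 0.000475 with an estimated correlation). Among 10 neutrophil-attracting chemokines and myeloid growth factors only Ccl3, which encodes a leukocyte chemoattractant, was called, at 0.796 ± 0.680 and 12.7 ± 8.01 CPM (log2 fold change 3.95 ± 0.82, edgeR BH-adjusted p = 0.0148). Adjusted over the list alone, 3 of these genes rose and 1 fell. The ND mean of Ccl3 was under 1 CPM, so the size of its log2 fold change rests on few counts. For the chemokine list camera gave BH-adjusted p = 0.0115, and adjusted p = 0.47 with an estimated correlation. The C-type lectin receptor gene Clec4d was the 1 called member of 16 pattern recognition genes, at 4.17 ± 2.32 and 27.4 ± 20.8 CPM (2 called when adjusted over the list alone). For the pattern recognition list camera gave BH-adjusted p = 0.00106, and adjusted p = 0.185 with an estimated correlation. Nfkbiz, a nuclear regulator of NF-kB target genes, rose from 64.3 ± 7.34 to 129 ± 23.6 CPM and was the 1 called member of 8 IL-17 and IL-23 axis genes (2 when adjusted over the list alone). For the IL-17 and IL-23 list camera gave BH-adjusted p = 0.0115, and adjusted p = 0.131 with an estimated correlation.

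Of 22 cornified envelope and terminal differentiation genes, 3 rose with the diet in PMA-treated skin, and adjusted over the list alone 8 rose and 1 fell. For the cornified envelope list camera gave BH-adjusted p = 9.92e-05, and adjusted p = 0.207 with an estimated correlation. Krt1, a keratin of suprabasal keratinocytes (chromosome 15, 101845426 to 101850794), rose from 1045 ± 156 to 2995 ± 426 CPM. Flg, encoding the filament-aggregating protein filaggrin, rose from 133 ± 33.3 to 348 ± 109 CPM, and Casp14, a caspase that takes part in filaggrin processing, from 171 ± 52.2 to 364 ± 61.1 CPM. The hyperproliferation-associated keratinocyte list had 1 called member of 14, the fatty acid-binding protein gene Fabp5 (222 ± 33.2 to 451 ± 160.1 CPM), with 6 higher and 1 lower when adjusted over the list alone. For the hyperproliferation list camera gave BH-adjusted p = 1.58e-06, and adjusted p = 0.185 with an estimated correlation. Of 22 cell cycle genes 2 rose, the mitotic genes Ube2c (11.3 ± 1.33 to 29.4 ± 14.6 CPM) and Ccnb2 (32.4 ± 7.13 to 66.6 ± 20.6 CPM), and 12 rose when adjusted over the list alone. For the cell cycle list camera gave BH-adjusted p = 2.96e-08, and adjusted p = 0.192 with an estimated correlation. Of 12 NRF2 targets, genes of the response to oxidants, 2 rose and 3 did so when adjusted over the list alone. For the NRF2 list camera gave BH-adjusted p = 0.00597, and adjusted p = 0.0746 with an estimated correlation. The called genes were Slc7a11, a cystine transporter gene (15.9 ± 3.66 to 85.8 ± 31.6 CPM, log2 fold change 2.43 ± 0.40), and the peroxiredoxin gene Prdx1 (404 ± 61.5 to 616 ± 72.6 CPM).

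Of 14 fibroblast matrix genes, 6 fell with the diet in PMA-treated skin and none rose, and 11 fell when adjusted over the list alone. For the fibroblast matrix list camera gave BH-adjusted p = 9.83e-09, and adjusted p = 0.0577 with an estimated correlation. Beside Col1a1 these included the fibronectin gene Fn1 (539.7 ± 132 to 283 ± 82.1 CPM). The microfibril gene Mfap5 (27.7 ± 4.05 to 14.6 ± 2.60 CPM) and the type V collagen gene Col5a2 (177 ± 33.5 to 93.9 ± 15 CPM) fell likewise. Cartilage genes moved likewise, with 5 of 9 lower and 7 lower when adjusted over the list alone. For the cartilage list camera gave BH-adjusted p = 6.16e-06, and adjusted p = 0.131 with an estimated correlation. Examples were the type II collagen gene Col2a1 (37.1 ± 17.1 to 11.9 ± 4.20 CPM) and Col9a1 (16.2 ± 3.44 to 7.94 ± 1.55 CPM). The proteoglycan gene Acan fell from 90.6 ± 25.8 to 48.2 ± 8.85 CPM and Comp from 88.6 ± 23.4 to 48.6 ± 12.8 CPM. Of 10 genes of type 2 immunity and alternative activation 3 fell and none rose, with 6 lower when adjusted over the list alone. For the type 2 immunity list camera gave BH-adjusted p = 3.42e-06, and adjusted p = 0.0284 with an estimated correlation. The called genes were Ccl24, the epithelial cytokine gene Tslp (28.6 ± 5.39 to 10.5 ± 4.63 CPM) and Retnla, a marker of alternatively activated macrophages (5.26 ± 2.39 to 1.01 ± 0.501 CPM). Retnla was below the level set for naming and was picked after its values were seen. Of 15 monocyte and macrophage genes 2 fell, also when adjusted over the list alone. The scavenger receptor gene Cd163 fell from 120.5 ± 23.2 to 58.3 ± 15.5 CPM and the growth factor receptor gene Csf1r from 212 ± 43.6 to 132 ± 23.4 CPM. For the macrophage list camera gave BH-adjusted p = 0.0317, and adjusted p = 0.485 with an estimated correlation. The dendritic cell lectin gene Cd209a (69.4 ± 18.4 to 33.3 ± 13.3 CPM), the adipocyte gene Cfd (109.5 ± 49.0 to 46.6 ± 10.8 CPM) and the clock repressor gene Nr1d1 (306 ± 23.8 to 213 ± 36.7 CPM) were also lower. They were the 1 called member each of 12 Langerhans and dendritic cell genes (1 lower when adjusted over the list alone, camera BH-adjusted p = 0.329), 14 adipocyte genes (2 lower when adjusted over the list alone) and 15 clock genes (5 lower when adjusted over the list alone). For the clock list camera gave BH-adjusted p = 0.019, and adjusted p = 0.411 with an estimated correlation. Of 13 skeletal muscle genes none was called (1 lower when adjusted over the list alone). For the adipocyte list camera gave BH-adjusted p = 0.0158, and adjusted p = 0.429 with an estimated correlation. For the skeletal muscle list camera gave BH-adjusted p = 0.000232, and adjusted p = 0.429 with an estimated correlation.

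The largest called increases with the diet in PMA-treated skin included the lipoxygenase gene Alox8 (49.2 ± 37.1 to 399.7 ± 130.5 CPM) and the antimicrobial S100 gene S100a7a (3.57 ± 0.799 to 35.9 ± 21.8 CPM). Uox, the urate oxidase gene, rose from 5.51 ± 5.59 to 48.8 ± 26.1 CPM and Fetub from 1.77 ± 0.420 to 16 ± 6.72 CPM. The hair keratin gene Krt32 rose from 1.25 ± 1.01 to 15.8 ± 20.8 CPM (log2 fold change 3.59), with 47.0 CPM in HFD_PMA replicate 1 and 5.01 to 6.02 in the other 3. Without that library its log2 fold change was 2.06 (edgeR BH-adjusted p = 0.0835). Cyp2e1, a cytochrome P450 (chromosome 7, 140763739 to 140774987), fell from 28.4 ± 10 to 6.68 ± 0.828 CPM (log2 fold change -2.09 ± 0.27, edgeR BH-adjusted p = 0.00107). Cd209e (17.7 ± 4.15 to 4.16 ± 1.36 CPM) and Wdfy4 (14.5 ± 6.95 to 3.83 ± 1.21 CPM) fell as well. The desmosome gene Dsg1c (12.5 ± 4.59 to 3.52 ± 0.977 CPM) and Serpina3g (19.9 ± 4.16 to 6.20 ± 2.52 CPM) fell too. In all, 387 of 17604 genes were called by edgeR's quasi-likelihood test, 166 higher and 221 lower in HFD. The split was 203 to 183 with RLE size factors, 446 to 404 with DESeq2 and 192 to 185 with the mitochondrial genes left out. These genes held 2.28 to 3.06% of the counts in HFD_PMA and 1.35 to 2.44% in ND_PMA libraries. Growing hair shaft and inner root sheath genes were unequal between single libraries. Their mean log2 CPM was 6.51, 2.54, 1.49 and 1.47 in HFD_PMA replicates 1 to 4 and -1.20, 2.73, -0.54 and -0.03 in ND_PMA replicates 1 to 4. None of the 17 was called, 11 were higher when adjusted over the list alone, and camera gave BH-adjusted p = 0.00248 (adjusted p = 0.504 with an estimated correlation). The count was 157 without HFD_PMA replicate 2, 208 without ND_PMA replicate 3 and 238 without ND_PMA replicate 4. It was 155 in a fit of the 8 libraries alone, 850 with DESeq2 and 100 without the 4 libraries highest in hair genes. Of the 47 genes followed, 25 lost their call without some library, from 7 without HFD_PMA replicate 4 to 23 without HFD_PMA replicate 2, with highest edgeR BH-adjusted p between 0.0549 and 0.156. Ccl3, Clec4d, Nfkbiz, Fabp5, Prdx1, Ube2c, Ccnb2, Col1a1, Col9a1, Acan, Comp, Tslp, Retnla, Csf1r, Cd209a, Cfd, Nr1d1, Alox8, S100a7a, Krt32, Wdfy4 and Dsg1c were among them.

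**Figure D1:**
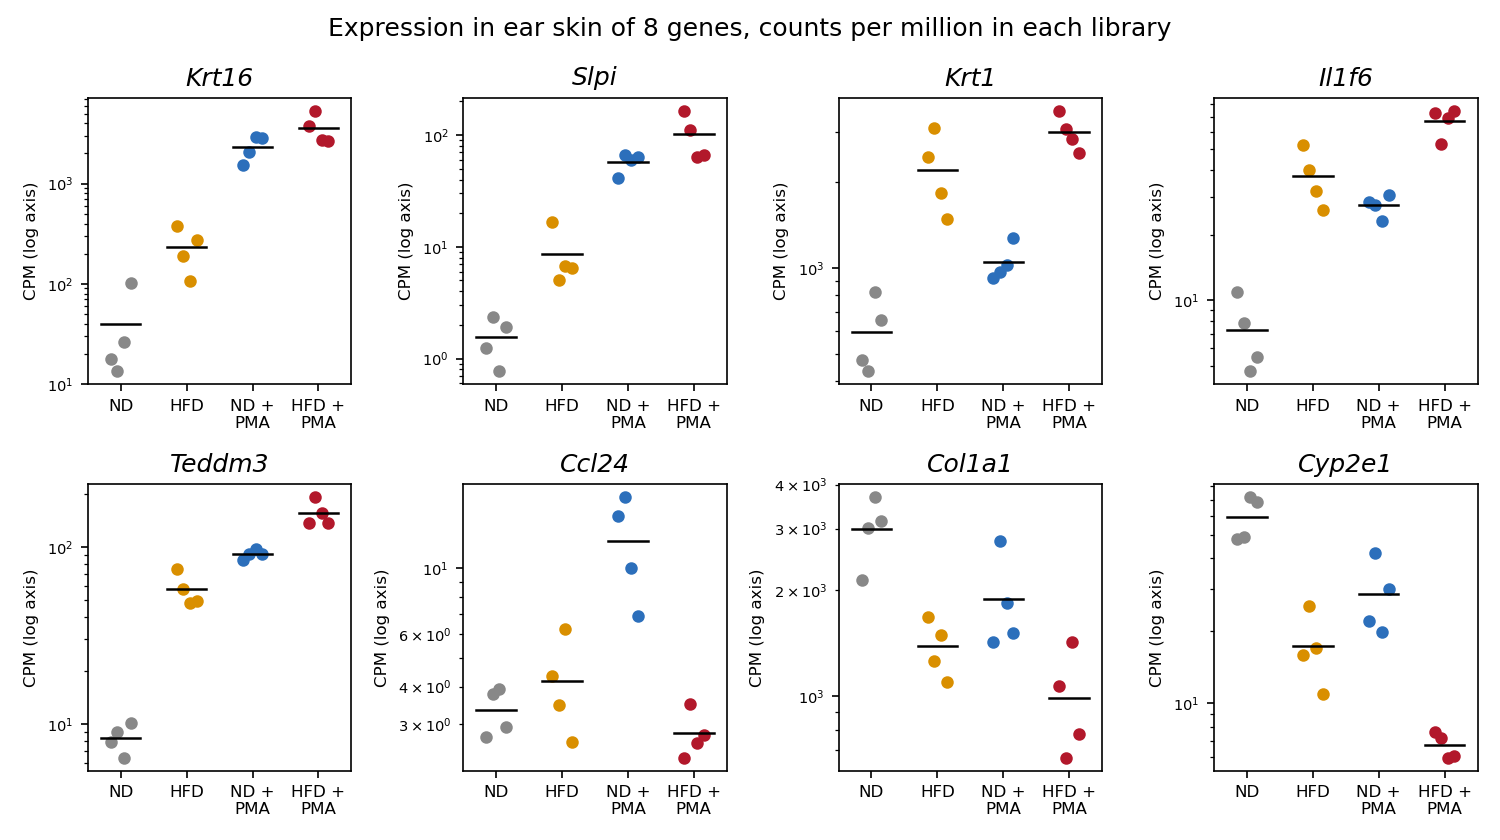
CPM on a log axis of 8 genes in each of the 16 libraries, with dots for libraries, a line for the group mean and the groups untreated ND, untreated HFD, PMA-treated ND and PMA-treated HFD along the horizontal axis. Teddm3 averaged 8.36, 57.7, 91.3 and 155 CPM in these groups, and Ccl24 3.34, 4.16, 12.3 and 2.79 CPM.

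The second comparison asked what the diet changed in skin without PMA. In untreated ears of HFD mice 10 of 22 cornified envelope genes and 5 of 15 IL-1 family genes were higher, and 7 of 14 fibroblast matrix genes lower, than in those of ND mice. Flg (chromosome 3, 93273523 to 93293686) rose from 155 ± 23.5 to 679 ± 185 CPM (log2 fold change 2.13 ± 0.23, edgeR BH-adjusted p = 2.10e-05). Krt1 rose from 597 ± 178 to 2209 ± 711 CPM (log2 fold change 1.89 ± 0.21, edgeR BH-adjusted p = 3.85e-05). Il1f6 rose from 7.26 ± 2.82 to 37.4 ± 11.3 CPM (log2 fold change 2.37 ± 0.25, edgeR BH-adjusted p = 2.10e-05). Col1a1 fell from 3000 ± 638 to 1384 ± 257 CPM (log2 fold change -1.12 ± 0.23, edgeR BH-adjusted p = 0.0083).

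Of 22 cornified envelope and terminal differentiation genes 10 rose with the diet in untreated skin and none fell, and 15 rose when adjusted over the list alone. For the cornified envelope list camera gave BH-adjusted p = 4.54e-18, and adjusted p = 0.016 with an estimated correlation. Casp14 rose from 108 ± 11.2 to 322 ± 94.3 CPM and the late cornified envelope gene Lce1a1 from 73.1 ± 6.92 to 154 ± 12.4 CPM. Of 14 hyperproliferation-associated keratinocyte genes 7 rose, and 9 when adjusted over the list alone. For the hyperproliferation list camera gave BH-adjusted p = 2.35e-08, and adjusted p = 0.131 with an estimated correlation. Called genes included the envelope precursor genes Sprr1b (8.62 ± 3.35 to 64.4 ± 29.8 CPM) and Sprr1a (83.0 ± 21.5 to 229 ± 81.0 CPM). The wound-associated keratin gene Krt16 rose from 39.8 ± 41.7 to 236 ± 115 CPM and the protease inhibitor gene Slpi from 1.57 ± 0.707 to 8.67 ± 5.31 CPM. Of 15 IL-1 family and inflammatory cytokine genes 5 rose and 6 did so when adjusted over the list alone. For the IL-1 family list camera gave BH-adjusted p = 2.22e-05, and adjusted p = 0.016 with an estimated correlation. Il18 rose from 30.1 ± 1.96 to 66.8 ± 6.35 CPM, Il1f8, encoding IL-36 beta, from 37.4 ± 11.4 to 81.0 ± 5.79 CPM and Il1f9 from 75.1 ± 11.4 to 129 ± 12.5 CPM. Of 8 IL-17 and IL-23 axis genes 3 rose, with 3 higher and 2 lower when adjusted over the list alone. The list as a whole did not pass camera (BH-adjusted p = 0.353). The called genes were the chemokine gene Ccl20 (1.46 ± 0.456 to 9.21 ± 2.13 CPM), Nfkbiz (44.5 ± 14.6 to 98 ± 20.9 CPM) and Zc3h12a. The last encodes an RNase that degrades cytokine mRNAs and rose from 10.2 ± 2.77 to 27.9 ± 7.80 CPM. The chemokine receptor gene Cxcr2, expressed by neutrophils, rose from 6.35 ± 2.38 to 18.7 ± 2.74 CPM. The 9 neutrophil genes as a list did not pass (2 higher, also when adjusted over the list alone, camera BH-adjusted p = 0.717).

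Of 17 fatty acid oxidation and PPAR target genes 4 rose with the diet in untreated skin, also when adjusted over the list alone. The mitochondrial dehydrogenase gene Acadl rose from 67.0 ± 7.40 to 108 ± 20.8 CPM. For the fatty acid oxidation list camera gave BH-adjusted p = 0.00152, and adjusted p = 0.184 with an estimated correlation. Of 19 epidermal barrier lipid genes 3 rose and 4 when adjusted over the list alone. They included the ceramide enzyme genes Degs2 (22.1 ± 9.66 to 58.4 ± 15.1 CPM) and Cers3 (152 ± 15.8 to 213 ± 12.3 CPM). For the barrier lipid list camera gave BH-adjusted p = 0.000907, and adjusted p = 0.349 with an estimated correlation. Of 17 cholesterol synthesis genes none was called and 4 were higher when adjusted over the list alone. For the cholesterol synthesis list camera gave BH-adjusted p = 3.55e-05, and adjusted p = 0.346 with an estimated correlation. Of 19 sebaceous gland genes 1 rose and 2 fell, 3 and 5 when adjusted over the list alone, and the list did not pass camera (BH-adjusted p = 0.29). The fatty acid elongase gene Elovl5 fell from 262 ± 44.8 to 137 ± 17.8 CPM and the desaturase gene Scd3 from 28.5 ± 5.16 to 8.12 ± 2.16 CPM. Of 14 adipocyte genes 2 fell, Car3 (1010 ± 136 to 624 ± 162 CPM) and the lipid droplet gene Cidec (134 ± 23.2 to 83.8 ± 21.1 CPM), and 4 fell when adjusted over the list alone. For the adipocyte list camera gave BH-adjusted p = 2.36e-05, and adjusted p = 0.184 with an estimated correlation. Of 14 fibroblast matrix genes 7 fell, and 11 when adjusted over the list alone, among them Col1a2 (1961 ± 305 to 1079 ± 108 CPM) and Col3a1 (2170 ± 461 to 1200 ± 185 CPM). For the fibroblast matrix list camera gave BH-adjusted p = 1.41e-09, and adjusted p = 0.0321 with an estimated correlation. None of 12 endothelial and none of 9 cartilage genes was called, and 2 and 5 were lower when adjusted over the list alone. For the endothelial list camera gave BH-adjusted p = 0.00196, and adjusted p = 0.127 with an estimated correlation. For the cartilage list camera gave BH-adjusted p = 0.00585, and adjusted p = 0.349 with an estimated correlation. The NRF2 list had 1 called member, Prdx1 (288 ± 58.5 to 453 ± 17.8 CPM), with 3 of 12 higher when adjusted over the list alone. For the NRF2 list camera gave BH-adjusted p = 0.000174, and adjusted p = 0.016 with an estimated correlation.

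Among the largest called changes with the diet in untreated skin, the kallikrein protease gene Klk13 rose from 4.04 ± 2.19 to 39.5 ± 14.7 CPM (log2 fold change 3.28 ± 0.37, edgeR BH-adjusted p = 7.38e-05). Alox8 rose from 2.06 ± 2.06 to 38.6 ± 18.1 CPM and the neuronal tubulin gene Tubb3 from 0.940 ± 0.430 to 12.1 ± 4.48 CPM. Tdh, a threonine dehydrogenase gene, rose from 2.06 ± 0.800 to 14.7 ± 2.75 CPM and Sprr2h from 1.25 ± 0.429 to 12.5 ± 8.22 CPM. Paqr7, a membrane progestin receptor gene, fell from 374 ± 135 to 99.9 ± 54.7 CPM. Cyp2e1 fell from 59.6 ± 12.6 to 17.3 ± 6.05 CPM and the complement gene C7 from 63.1 ± 12.4 to 21.7 ± 4.17 CPM. Hair genes were also called, with 2 of 17 growing hair shaft and inner root sheath genes higher and 17 of 17 when adjusted over the list alone. For the hair list camera gave BH-adjusted p = 1.26e-05, and adjusted p = 0.432 with an estimated correlation. The hair keratin gene Krt34 averaged 0.0240 CPM in ND and 6.36 ± 5.79 CPM in HFD mice. Padi3, whose product modifies hair proteins, averaged 0.0517 and 7.39 ± 5.70 CPM, and Lyg2, a lysozyme g-like gene, 0.0280 and 27.2 ± 31.7 CPM. The mean log2 CPM of the hair list was 6.30, 5.6, 1.88 and 4.09 in HFD_cont replicates 1 to 4 and lay between -0.81 and 0.69 in the ND_cont libraries. In all 691 genes were called by edgeR's quasi-likelihood test, 505 higher and 186 lower in HFD, with 536 higher and 334 lower by limma voom. Counts in rRNA genes made up 0.421 to 0.549% of a library in HFD_cont and 0.229 to 0.364% in ND_cont, and counts in mitochondrial genes 2.09 to 2.93% and 1.48 to 2.18%. With the mitochondrial genes left out 671 genes were called. This comparison overlapped with the library ID series, and with the series as a covariate 179 genes were called (163 higher, 16 lower, 149 of them among the 691). In a contrast of RHS libraries alone HFD_cont replicate 1 was the lone HFD library and was assumed to vary like the other groups. That fit kept the PMA-treated libraries, all RHP. Without the 4 libraries highest in hair genes, which leaves HFD_cont replicate 3 as the lone HFD library on the same assumption, 22 were called. Without 1 library the count was 332 (ND_cont replicate 4), 347 (ND_cont replicate 3), 405 (HFD_cont replicate 4), 419 (HFD_cont replicate 3), 430 (HFD_cont replicate 1) or 453 (HFD_cont replicate 2). Of the 54 genes followed, 24 lost their call without some library, 17 of them without ND_cont replicate 3 and 17 without ND_cont replicate 4, with highest edgeR BH-adjusted p between 0.0502 and 0.181. Krt16, Cers3, Col3a1, Scd3, Car3, Cidec, Padi3, Krt34 and Lyg2 were among them. With the series as a covariate 35 of the 54 lost their call and 1 reversed, and with the hair list mean as a covariate 22 lost it.

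**Figure D2:**
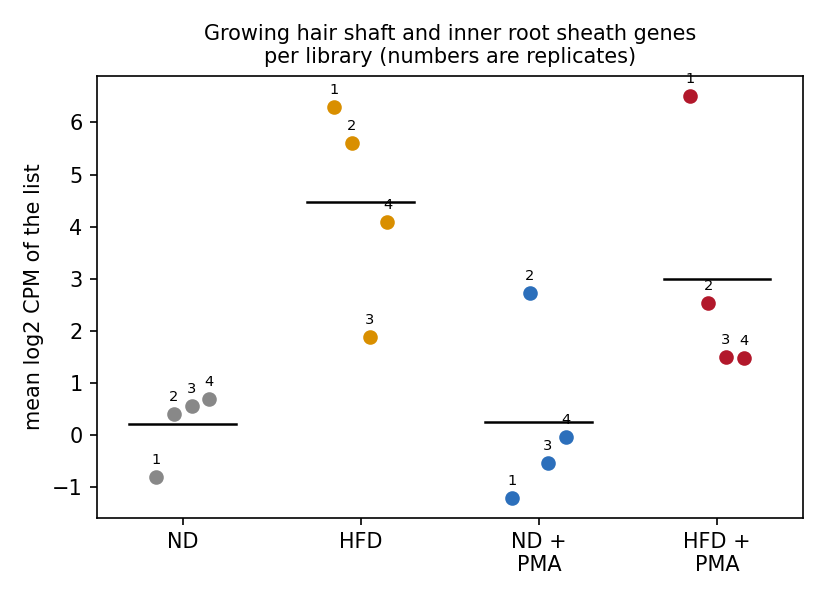
Mean log2 CPM of the growing hair shaft and inner root sheath list in each library, with digits for the replicate numbers, a line for the group mean and the 4 groups along the horizontal axis. The 4 libraries above 4 are HFD_cont replicates 1, 2 and 4 and HFD_PMA replicate 1, and the 4 untreated ND libraries lie between -0.81 and 0.69.

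The third comparison gave the response to PMA in ND mice. All 22 cell cycle genes and 12 of 14 hyperproliferation-associated keratinocyte genes were higher, and 10 of 14 adipocyte genes lower, in PMA-treated than in untreated ND ears. Krt16 (chromosome 11, 100246091 to 100248902) rose from 39.8 ± 41.7 to 2332 ± 659.6 CPM (log2 fold change 5.88 ± 0.70, edgeR BH-adjusted p = 0.000132). Slpi rose from 1.57 ± 0.707 to 57.7 ± 11.3 CPM (log2 fold change 5.18 ± 0.43, edgeR BH-adjusted p = 1.13e-07). Top2a, a topoisomerase gene of dividing cells (chromosome 11, 98992943 to 99024189), rose from 27.6 ± 5.71 to 113 ± 27.4 CPM (log2 fold change 2.03 ± 0.22, edgeR BH-adjusted p = 4.53e-06). Adipoq, the adipocyte hormone adiponectin, fell from 71.4 ± 17.2 to 27.6 ± 7.31 CPM (log2 fold change -1.37 ± 0.22, edgeR BH-adjusted p = 0.000286).

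All 22 measured cell cycle genes rose with PMA in ND mice, also when adjusted over the list alone. For the cell cycle list camera gave BH-adjusted p = 2.26e-21, and adjusted p = 0.0509 with an estimated correlation. The nucleotide synthesis gene Rrm2 rose from 36.2 ± 5.40 to 154 ± 14.9 CPM and the replication helicase gene Mcm5 from 38.5 ± 12.6 to 162 ± 22.6 CPM. Of 14 hyperproliferation-associated keratinocyte genes 12 rose, and adjusted over the list alone 13 rose and 1 fell. Krt6a rose from 71.6 ± 65.8 to 1366 ± 320.4 CPM and Krt6b (chromosome 15, 101676023 to 101680287) from 29.8 ± 53.7 to 1481 ± 497 CPM. ND_cont replicate 4 stood at 170 CPM for Krt6a (33.3 to 43.9 in the others) and 110 for Krt6b (2.08 to 3.94), and without it the log2 fold changes were 5.10 instead of 4.26 and 8.90 instead of 5.64. For the hyperproliferation list camera gave BH-adjusted p = 3.43e-12, and adjusted p = 0.062 with an estimated correlation. Of 22 cornified envelope genes 6 rose and 1 fell, 7 and 3 when adjusted over the list alone, and the list did not pass camera (BH-adjusted p = 0.555). Krt1 rose to 1045 ± 156 CPM and the desquamation protease gene Klk7 from 648 ± 93.0 to 1343 ± 136 CPM, while Lce1m fell from 175 ± 40.1 to 70.5 ± 8.30 CPM. Of 12 NRF2 targets 5 rose and 7 when adjusted over the list alone, such as the glutathione reductase gene Gsr (48.6 ± 5.56 to 81.4 ± 8.73 CPM). For the NRF2 list camera gave BH-adjusted p = 0.00216, and adjusted p = 0.0509 with an estimated correlation. Of 15 IL-1 family and inflammatory cytokine genes 5 rose and 6 when adjusted over the list alone, Il1f6 among them at 27.5 ± 3.08 CPM after PMA. For the IL-1 family list camera gave BH-adjusted p = 0.015, and adjusted p = 0.125 with an estimated correlation.

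Of 10 neutrophil-attracting chemokines and myeloid growth factors 4 rose with PMA in ND mice and 6 when adjusted over the list alone. Cxcl5 (chromosome 5, 90759360 to 90761624) stood at 0.421 ± 0.842 and 15.5 ± 14.6 CPM, and Ccl7, a monocyte attractant, at 3.58 ± 0.899 and 24.5 ± 14.4 CPM. Of the untreated ND libraries only replicate 4 held Cxcl5 counts (1.68 CPM, 0 in the others). The log2 fold change of 5.23 thus rests on that library, and without it no ratio can be formed. The mean log2 CPM of this list was 3.35 in ND_PMA replicate 2 and 1.21 to 1.56 in the other 3. For the chemokine list camera gave BH-adjusted p = 0.00727, and adjusted p = 0.393 with an estimated correlation. Of 9 neutrophil genes 4 rose, and 6 when adjusted over the list alone. The G-CSF receptor gene Csf3r rose from 3.12 ± 2.09 to 33.4 ± 18.9 CPM and Cxcr2 from 6.35 ± 2.38 to 35.0 ± 4.54 CPM. For the neutrophil list camera gave BH-adjusted p = 0.000721, and adjusted p = 0.244 with an estimated correlation. Of 6 blood and red cell genes 1 rose, and 2 when adjusted over the list alone. For the blood list camera gave BH-adjusted p = 0.0191, and adjusted p = 0.388 with an estimated correlation. Of 15 monocyte and macrophage genes 6 rose and 8 when adjusted over the list alone. For the macrophage list camera gave BH-adjusted p = 0.000766, and adjusted p = 0.28 with an estimated correlation. The monocyte chemokine receptor gene Ccr2 rose from 18.3 ± 2.02 to 121 ± 34.1 CPM and Cd68, a lysosomal protein gene of macrophages, from 33.4 ± 9.03 to 77.3 ± 22.5 CPM. Of 10 type 2 immunity genes 6 rose and 7 when adjusted over the list alone. For the type 2 immunity list camera gave BH-adjusted p = 3.47e-07, and adjusted p = 0.0262 with an estimated correlation. The genes that rose included the chitinase-like gene Chil3 (2.55 ± 2.68 to 63.0 ± 20.1 CPM) and the chemokine gene Ccl22 (4.37 ± 1.36 to 31.4 ± 7.35 CPM). Tslp (4.42 ± 1.75 to 28.6 ± 5.39 CPM) and Ccl24 (3.34 ± 0.613 to 12.3 ± 4.70 CPM) were among them too. The protease inhibitor gene Timp1 rose from 1.95 ± 1.09 to 36.8 ± 5.51 CPM and the stromelysin gene Mmp3 from 68.6 ± 9.56 to 303 ± 61.4 CPM. They were the 2 called members of 12 matrix protease genes, and 3 rose when adjusted over the list alone. For the matrix protease list camera gave BH-adjusted p = 0.000741, and adjusted p = 0.175 with an estimated correlation. Of 16 pattern recognition genes 4 rose, and 6 when adjusted over the list alone. For the pattern recognition list camera gave BH-adjusted p = 0.00814, and adjusted p = 0.244 with an estimated correlation.

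Of 14 adipocyte genes 10 fell with PMA in ND mice and 12 fell when adjusted over the list alone, with the leptin gene Lep going from 44.1 ± 4.44 to 11.9 ± 6.43 CPM. For the adipocyte list camera gave BH-adjusted p = 3.07e-09, and adjusted p = 0.062 with an estimated correlation. Of 19 sebaceous gland genes 8 fell and 13 when adjusted over the list alone, among them the desaturase gene Scd1 (6380 ± 1096 to 2971 ± 619.9 CPM). For the sebaceous gland list camera gave BH-adjusted p = 1.14e-06, and adjusted p = 0.175 with an estimated correlation. Of 15 clock genes 7 fell and 9 when adjusted over the list alone, such as Npas2 (11.4 ± 1.52 to 4.50 ± 1.15 CPM) and Cry2 (264 ± 40.3 to 164 ± 18.8 CPM). For the clock list camera gave BH-adjusted p = 5.08e-06, and adjusted p = 0.106 with an estimated correlation. Of 12 follicle stem cell and outer root sheath genes 3 fell, and adjusted over the list alone 1 rose and 3 fell, with the keratin gene Krt15 going from 5046 ± 664 to 1551 ± 166 CPM. For the follicle stem cell list camera gave BH-adjusted p = 0.0191, and adjusted p = 0.175 with an estimated correlation. Of 9 cartilage genes 2 fell, also when adjusted over the list alone. For the cartilage list camera gave BH-adjusted p = 0.00986, and adjusted p = 0.325 with an estimated correlation. Among the largest called changes the photoreceptor cadherin gene Cdhr1 rose from 0.492 ± 0.805 to 34.7 ± 5.48 CPM and the neutrophil gene Cd177 from 0.171 ± 0.159 to 10.4 ± 3.87 CPM. Gpm6a, a neuronal membrane gene, fell from 13.7 ± 2.36 to 2.42 ± 1.64 CPM. In all 2279 genes were called by edgeR's quasi-likelihood test, 1577 higher and 702 lower, and with upper-quartile factors the split was 1320 to 938. All untreated ND libraries carried the RHS prefix and all PMA-treated ND libraries RHP, so no within-series value exists. With the series as a covariate, which HFD_cont replicate 1 alone separates from the groups, 453 genes were called (388 higher, 65 lower, 411 of them among the 2279). Of the genes named for this comparison, Krt1 lost its call without ND_cont replicate 1 (log2 fold change 0.67, edgeR BH-adjusted p = 0.0609). With the series as a covariate 32 of the 56 genes followed lost their call.

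The fourth comparison gave the response to PMA in HFD mice. Genes higher in PMA-treated than in untreated HFD ears included S100a8, S100a9, Ccl3 and 21 of 22 cell cycle genes, and genes that were lower included Lor, 7 of 19 sebaceous gland genes and 6 of 9 cartilage genes. S100a8, which encodes a subunit of calprotectin, rose from 8.75 ± 9.17 to 363 ± 278 CPM (log2 fold change 5.43 ± 1.00, edgeR BH-adjusted p = 0.0036). S100a9, which encodes the other, rose from 4.71 ± 4.14 to 176 ± 139.6 CPM (log2 fold change 5.28 ± 0.88, edgeR BH-adjusted p = 0.00179). Ccl3 (chromosome 11, 83647844 to 83649355) stood at 0.212 ± 0.356 CPM without and 12.7 ± 8.01 CPM with PMA (log2 fold change 6.09 ± 0.98, edgeR BH-adjusted p = 0.000381). Its mean without PMA was under 1 CPM, so the size of this log2 fold change rests on few counts. The cornified envelope gene Lor, encoding loricrin, fell from 1127 ± 72.1 to 544 ± 143 CPM (log2 fold change -1.05 ± 0.19, edgeR BH-adjusted p = 0.00102).

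Of 22 cell cycle genes 21 rose with PMA in HFD mice, and 22 when adjusted over the list alone. Top2a rose from 44.7 ± 11.6 to 184 ± 46.8 CPM, the mitotic kinase gene Plk1 from 15.7 ± 5.11 to 69.6 ± 21.6 CPM and the cyclin gene Ccna2 from 23.3 ± 7.43 to 99.5 ± 33.5 CPM. For the cell cycle list camera gave BH-adjusted p = 1.12e-27, and adjusted p = 0.0281 with an estimated correlation. Of 14 hyperproliferation-associated keratinocyte genes 12 rose and 1 fell, the same numbers as when adjusted over the list alone, with Krt6b going from 81.9 ± 85.5 to 2356 ± 1230 CPM. For the hyperproliferation list camera gave BH-adjusted p = 5.82e-14, and adjusted p = 0.0629 with an estimated correlation. Of 22 cornified envelope genes 2 rose and 7 fell, and adjusted over the list alone 4 rose and 11 fell. For the cornified envelope list camera gave BH-adjusted p = 0.00292, and adjusted p = 0.269 with an estimated correlation. Flg2 fell from 927 ± 158 to 353 ± 206 CPM, Lce1m from 239.8 ± 49.2 to 60.2 ± 34.4 CPM and Lce1a1 from 154 ± 12.4 to 70.9 ± 18.7 CPM. Of 15 IL-1 family and inflammatory cytokine genes 6 rose and 1 fell, 8 and 1 when adjusted over the list alone. The alarmin gene Il33 rose from 99.2 ± 16.6 to 223 ± 96.5 CPM and Il1rn from 201 ± 15.3 to 348 ± 96.5 CPM. For the IL-1 family list camera gave BH-adjusted p = 6.58e-05, and adjusted p = 0.0281 with an estimated correlation. Of 12 NRF2 targets 5 rose, also when adjusted over the list alone. For the NRF2 list camera gave BH-adjusted p = 0.0126, and adjusted p = 0.109 with an estimated correlation.

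Of 10 neutrophil-attracting chemokines and myeloid growth factors 6 rose with PMA in HFD mice and 9 when adjusted over the list alone. Cxcl5 rose from 0.504 ± 0.262 to 22.1 ± 16.7 CPM and the neutrophil attractant gene Cxcl2 from 0.894 ± 0.587 to 12.5 ± 9.19 CPM. For the chemokine list camera gave BH-adjusted p = 6.18e-06, and adjusted p = 0.137 with an estimated correlation. Of 9 neutrophil genes 7 rose and 8 when adjusted over the list alone, with Csf3r going from 2.45 ± 1.59 to 43.2 ± 24.2 CPM and Lcn2 from 3.61 ± 1.26 to 64.4 ± 18.9 CPM. The mean log2 CPM of this list was 0.48 in HFD_PMA replicate 4 and 2.79 to 3.19 in the other 3. For the neutrophil list camera gave BH-adjusted p = 1.09e-05, and adjusted p = 0.112 with an estimated correlation. Of 16 pattern recognition genes 7 rose and 9 when adjusted over the list alone. Clec4d rose from 0.601 ± 0.612 to 27.4 ± 20.8 CPM and Clec4e from 1.49 ± 1.05 to 26.6 ± 20.5 CPM. The beta-glucan receptor gene Clec7a rose from 3.29 ± 1.33 to 33.4 ± 12.8 CPM and the LPS co-receptor gene Cd14 from 8.62 ± 2.72 to 48.6 ± 30.9 CPM. For the pattern recognition list camera gave BH-adjusted p = 5.02e-05, and adjusted p = 0.109 with an estimated correlation. Of 12 matrix protease genes 7 rose, also when adjusted over the list alone, with Mmp3 going from 33.8 ± 10 to 286 ± 137 CPM. For the matrix protease list camera gave BH-adjusted p = 0.000272, and adjusted p = 0.115 with an estimated correlation. Of 17 interferon-stimulated genes 3 rose and 4 when adjusted over the list alone, Oasl2 among them (3.90 ± 0.934 to 14.0 ± 10.2 CPM). For the interferon list camera gave BH-adjusted p = 0.00124, and adjusted p = 0.155 with an estimated correlation. Type 2 immunity genes rose in 4 of 10 cases and 5 when adjusted over the list alone. Chil3 rose from 1.10 ± 1.32 to 50.2 ± 16.3 CPM and the IL-4 receptor gene Il4ra from 46.4 ± 8.65 to 120 ± 42.1 CPM. For the type 2 immunity list camera gave BH-adjusted p = 0.00702, and adjusted p = 0.112 with an estimated correlation. Of 15 monocyte and macrophage genes 5 rose, also when adjusted over the list alone. For the macrophage list camera gave BH-adjusted p = 0.00274, and adjusted p = 0.282 with an estimated correlation. Acod1, which encodes the enzyme that makes itaconate in activated macrophages, rose from 0.452 ± 0.853 to 49.3 ± 34.9 CPM (log2 fold change 7.03 ± 1.38, edgeR BH-adjusted p = 0.00442). HFD_cont replicate 1 held 1.73 CPM of Acod1 and the other 3 at most 0.0773. The size of this log2 fold change thus rests on that library, and without it too few counts are left for a ratio. The coagulation factor gene F10 averaged 0.0580 CPM without and 10.2 ± 9.28 CPM with PMA.

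Of 19 sebaceous gland genes 7 fell with PMA in HFD mice and 11 when adjusted over the list alone, among them Far2, whose product makes fatty alcohols (540.3 ± 109.6 to 282 ± 59.6 CPM). For the sebaceous gland list camera gave BH-adjusted p = 1.10e-07, and adjusted p = 0.112 with an estimated correlation. The fatty acid hydroxylase gene Fa2h fell from 754 ± 119 to 264 ± 80.6 CPM. Of the 19 epidermal barrier lipid genes that include it 1 rose and 5 fell, 2 and 5 when adjusted over the list alone (camera BH-adjusted p = 0.0997). Of 14 adipocyte genes 7 fell and 10 when adjusted over the list alone, such as the lipoprotein lipase gene Lpl (128 ± 32.1 to 68.4 ± 8.48 CPM). For the adipocyte list camera gave BH-adjusted p = 1.79e-06, and adjusted p = 0.11 with an estimated correlation. Cartilage genes fell in 6 of 9 cases and 7 when adjusted over the list alone, among them Col11a2 (18.3 ± 5.23 to 5.95 ± 3.08 CPM). For the cartilage list camera gave BH-adjusted p = 2.95e-05, and adjusted p = 0.112 with an estimated correlation. Skeletal muscle genes fell in 4 of 13 cases and 7 when adjusted over the list alone, the myosin light chain gene Mylpf going from 78.2 ± 9.51 to 39.0 ± 9.27 CPM. For the skeletal muscle list camera gave BH-adjusted p = 3.52e-05, and adjusted p = 0.282 with an estimated correlation. Clock genes fell in 5 of 15 cases and 6 when adjusted over the list alone, Tef among them (224 ± 22.5 to 138 ± 28.1 CPM). For the clock list camera gave BH-adjusted p = 1.04e-05, and adjusted p = 0.109 with an estimated correlation. Of 17 growing hair shaft and inner root sheath genes 1 fell, also when adjusted over the list alone. For the hair list camera gave BH-adjusted p = 0.00397 as lower, and adjusted p = 0.516 with an estimated correlation. The serpin gene Serpina3b fell from 13.5 ± 3.24 to 0.936 ± 1.29 CPM and the aryl hydrocarbon receptor target Cyp1a1 from 45.6 ± 6.37 to 11.7 ± 5.61 CPM. In all 2101 genes were called by edgeR's quasi-likelihood test, 1292 higher and 809 lower, and with upper-quartile factors the split was 1114 to 984. Counts in rRNA genes made up 0.296 to 0.354% of a library in HFD_PMA and 0.421 to 0.549% in HFD_cont. The count was 1283 without HFD_PMA replicate 2, where Krt6b and Oasl2 were among 9 of the 68 followed genes that lost their call (highest edgeR BH-adjusted p between 0.0729 and 0.286). It was 1808 without HFD_cont replicate 1, where the contrast held RHP libraries alone and the fit kept the RHS libraries of ND mice. Leaving out the 4 libraries highest in hair genes left HFD_cont replicate 3 as the lone untreated HFD library, with its spread taken from the other groups. Krt6b also lost its call without HFD_cont replicate 2, 3 or 4 or HFD_PMA replicate 1 (edgeR BH-adjusted p from 0.0534 to 0.0823). The responses to PMA in the 2 diets share no library, and 935 genes were higher in both (116 for independent lists), 359 lower in both (32.3 for independent lists) and 0 opposite. Each gene's dispersion was estimated over all 16 libraries. The 2 sets of calls are thus not independent, and the numbers for independent lists are only a rough guide.

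**Figure D3:**
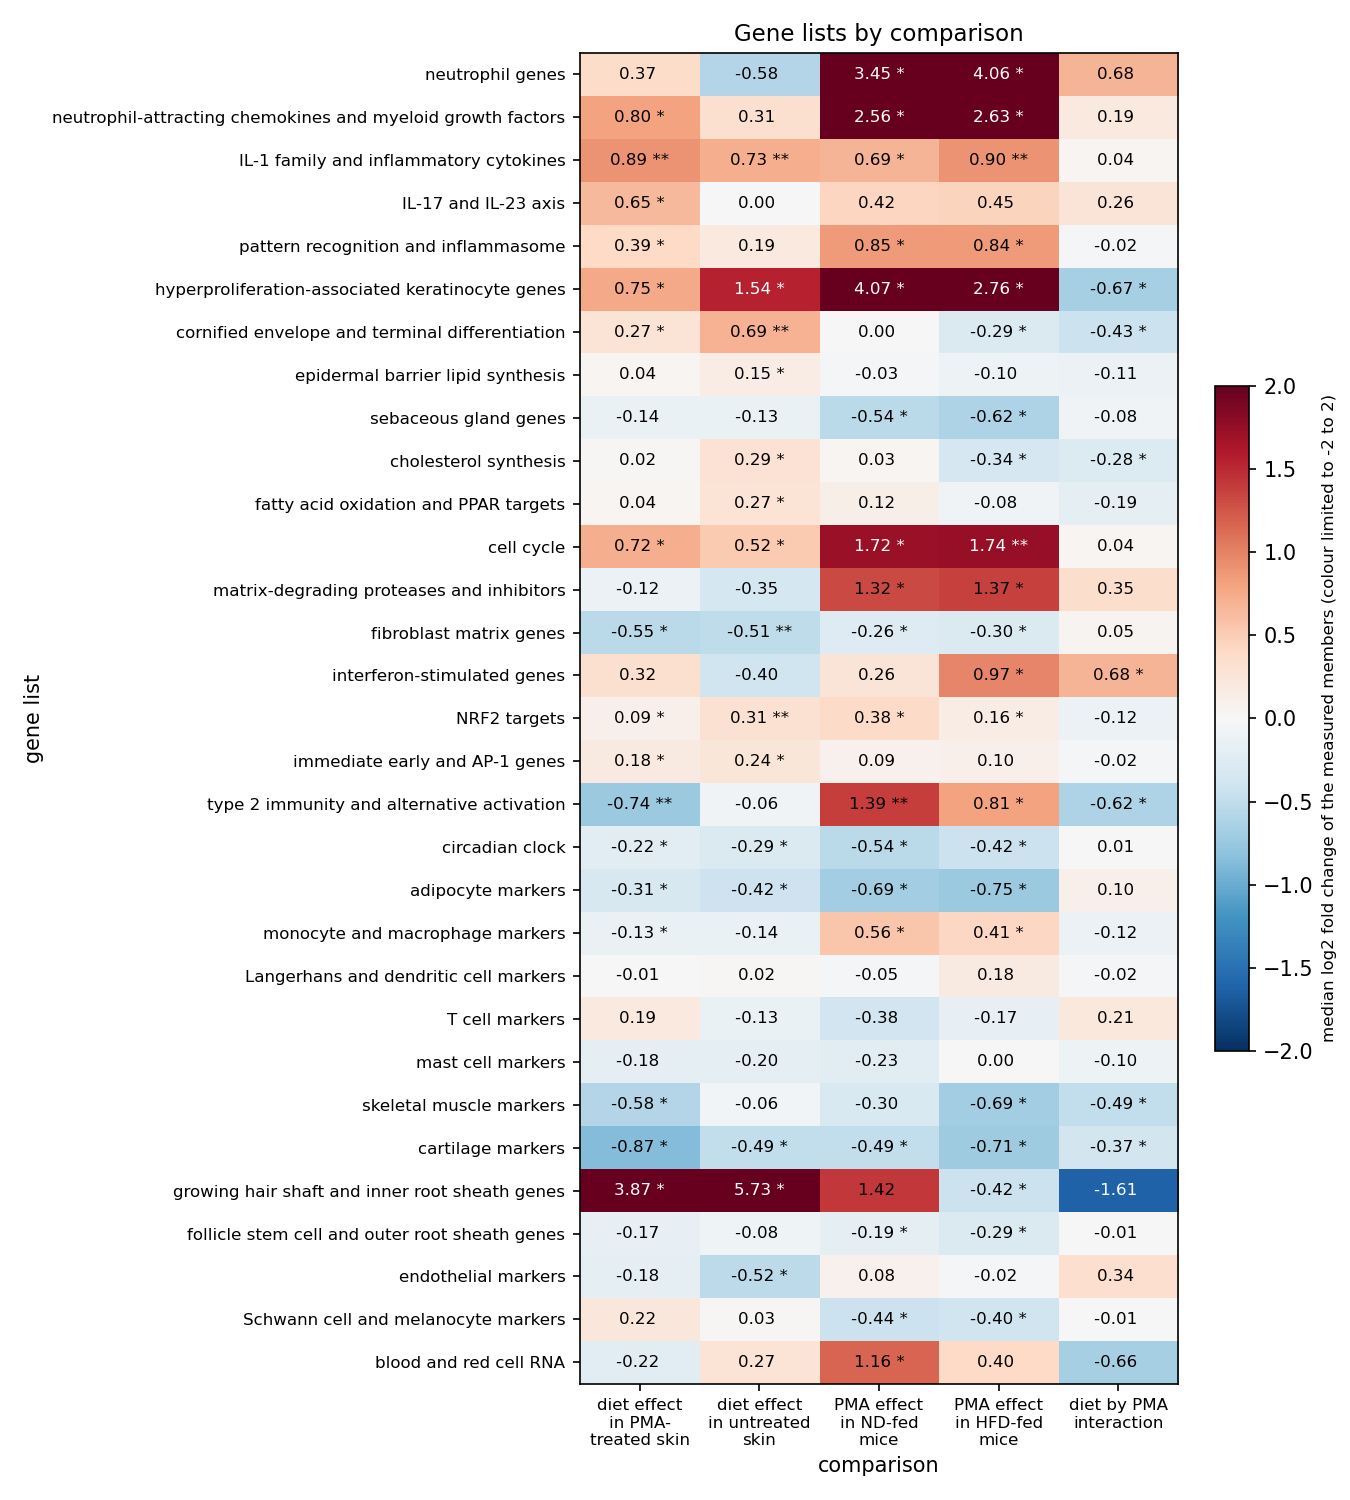
Median log2 fold change of the measured members of 31 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with the colour scale limited to -2 and 2. An asterisk marks a camera BH-adjusted p under 0.05 with the preset correlation and a double asterisk marks lists that also pass with an estimated correlation, and the cell cycle list passes in both responses to PMA with the preset correlation.

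The last comparison tested directly whether the response to PMA differed between the diets. A single gene passed, Teddm3 (chromosome 16, 21152655 to 21154000, 1 exon). It rose with PMA from 8.36 ± 1.56 to 91.3 ± 5.34 CPM in ND mice and from 57.7 ± 12.6 to 155 ± 25.4 CPM in HFD mice (interaction log2 fold change -2.02 ± 0.23, edgeR BH-adjusted p = 0.000538). Of all 17604 genes 815 had an unadjusted edgeR p under 0.05, and DESeq2 called 22. With the series as a covariate 2 genes passed, Teddm3 among them. The count was 4 without ND_cont replicate 2, 2 without ND_cont replicate 4, ND_PMA replicate 1 or HFD_PMA replicate 2, and 0 without the 4 libraries highest in hair genes, which leaves 1 untreated HFD library. Genes named above for 1 diet or treatment did not pass this edgeR test. Of the 9 genes followed for the interaction, DESeq2 called 3 that edgeR did not. Ccl24 had an interaction log2 fold change of -2.46 (edgeR BH-adjusted p = 0.187), Ccl3 of 5.67 (adjusted p = 0.278) and Sprr1b of -2.13 (adjusted p = 0.278). For Lor and Tslp it was -1.01 (edgeR BH-adjusted p = 0.523) and -1.70 (adjusted p = 0.740). The size of the Ccl3 value rests on few counts, since its mean in untreated HFD ears was under 1 CPM.

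No member of any list passed the interaction test over all genes, but 7 of 31 lists passed camera, and none of them passed with an estimated correlation or fry. The cornified envelope list had the smallest p, with lower interaction values than other genes (BH-adjusted p = 2.44e-09, adjusted p = 0.288 with an estimated correlation, 4 of 22 lower when adjusted over the list alone). The hyperproliferation-associated keratinocyte list (camera BH-adjusted p = 7.50e-05, adjusted p = 0.541 with an estimated correlation) and the cholesterol synthesis list (adjusted p = 0.000278 and 0.598 likewise) were lower. The type 2 immunity list (camera BH-adjusted p = 0.00496, adjusted p = 0.333 with an estimated correlation), the skeletal muscle list (0.00496 and 0.738) and the cartilage list (0.0209 and 0.632) were lower too. By the same tests the interferon-stimulated list was higher (0.00496 and 0.541). With the series as a covariate 9 lists passed camera, and of the 7 only the cornified envelope, hyperproliferation, cholesterol synthesis and type 2 immunity lists passed in the same direction. The skeletal muscle list turned to higher there (camera BH-adjusted p = 0.00767), and the interferon-stimulated and cartilage lists did not pass. Klk5, a protease gene of the cornified layer, showed the pattern of the first list at 162 ± 29.9 and 331 ± 15.8 CPM in untreated ND and HFD ears and 259 ± 24.0 and 291 ± 45.9 CPM after PMA (interaction log2 fold change -0.86, edgeR BH-adjusted p = 0.278). The lists that held with an estimated correlation were IL-1 family and type 2 immunity for the diet in PMA-treated skin, and cornified envelope, IL-1 family, fibroblast matrix and NRF2 for the diet in untreated skin. For PMA they were type 2 immunity in ND mice, and cell cycle and IL-1 family in HFD mice.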

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

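The tests of the library ID series, of hair growth, of tissue share and of 1 departing library were chosen only after the results were seen. The comparison of each library with the rest of its group and the interaction test were fixed before. A library stood apart where its gap to the nearest other library of its group exceeded 0.83 of the group's range. Of 788 groups of 4 values, 55 had such a library, and chance gives about 1 in 20 for continuous values. By kind these were 12 of 124 list means, 43 of 660 gene groups and 0 of 4 library totals. ND_PMA replicate 2 held 10, ND_cont replicate 4 held 9 and HFD_cont replicate 1 held 8. The chance rate does not cover genes whose other libraries in the group all held 0, where any count sets a library apart.

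The diet calls in untreated skin compare libraries of unequal series, unequal hair growth and unequal shares of rRNA and mitochondrial counts, and these shares were tested as a cause in no comparison. Against the series as the whole cause, 87 genes called between HFD_cont replicates 2 to 4 and ND_cont replicates 1 and 2 had a median signed log2 change of 1.06 (quartiles 0.71 to 1.68) between HFD_cont replicate 1 and ND_cont replicates 3 and 4, all of the RHS series, and 82 kept their sign (95th percentile of 1000 random sets 0.12). With the ND_cont pairs exchanged, 741 genes had 0.327 there against 0.932 where called (ratio of medians 0.35, and 1 before the exchange). All ND_cont libraries are RHS, so this drop may come from the ND_cont pairs or from the series, and a part of the series in the size stays open. Both values rest on HFD_cont replicate 1, the lone HFD library of the RHS series. On hair growth as the whole cause, the 691 called genes had a median signed log2 change of 0.846 (quartiles 0.636 to 1.15) with the hair list mean as a covariate. Without it the change was 0.752 (0.606 to 1.05), and 690 kept their sign with the covariate. Of the 691, 315 were called with the covariate, where the median SE was 0.221 instead of 0.166. That the median change was no smaller argues against a whole cause that follows the hair list mean in a straight line. All HFD_cont libraries (lowest 1.88) lay above all ND_cont libraries (highest 0.69) in that mean, so hair growth that acts otherwise cannot be told apart from the diet.

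The PMA response in ND mice runs along the library ID series. If the prefix were the whole cause, these genes should not move with PMA inside the RHP series. In HFD_PMA against HFD_cont replicates 2 to 4 the 2279 genes had a median signed log2 change of 0.635 (0.819 in ND mice) and 97.1% kept their sign, where the 95th percentile of random sets was 0.015. This argues against the prefix as the whole cause, and a contribution to the size of single changes stays open.

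Lower fibroblast matrix genes in PMA-treated HFD skin may reflect fewer matrix-producing cells in the piece, less expression per cell, or another library make-up. Leaving out ND_PMA replicate 2, whose list mean stood apart at 8.50 (the others 8.22 to 8.26), gave a difference of -0.482 instead of -0.545 on the log2 scale, so that library alone is not the cause. A list of basal keratinocyte genes written for this test differed by 0.068 (exact permutation p = 0.314, two-sided, 70 arrangements), too little to decide on a lower share of stromal tissue. Of 6 lists of other stromal types, adipocyte, mast cell, and Schwann cell and melanocyte markers departed from the fibroblast list by 0.265, 0.286 and 0.667 (each exact permutation p = 0.0286, the smallest possible, which 3 lists cannot bring under 0.05 after adjustment). By a Welch t test that can, added once these p were known, 0 of the 6 passed (BH-adjusted p = 0.0572, 0.0572 and 0.0591 for these 3), so a lower stromal share and lower expression cannot be told apart for these genes at 4 libraries per group, and tissue share was not tested in untreated skin.

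The response to PMA of Teddm3 differed between the diets by an interaction log2 fold change of -2.02. With the preset correlation alone 7 lists passed camera for the interaction, with BH-adjusted p of 2.44e-09 (cornified envelope), 7.50e-05 (hyperproliferation-associated keratinocyte genes), 0.000278 (cholesterol synthesis), 0.00496 (interferon-stimulated genes), 0.00496 (type 2 immunity), 0.00496 (skeletal muscle) and 0.0209 (cartilage). None of the 7 passed with an estimated correlation, and with the series as a covariate 4 of them passed in the same direction while skeletal muscle turned to higher (camera BH-adjusted p = 0.00767).

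Among list means in log2 CPM, HFD_PMA replicate 4 stood at 0.48 for neutrophil genes (the others 2.79 to 3.19), 5.93 for fatty acid oxidation (5.59 to 5.64) and 2.05 for T cell markers (1.78). ND_PMA replicate 2 stood at 3.35 for neutrophil-attracting chemokines (1.21 to 1.56), 5.75 for clock genes (5.97 to 6) and 5.22 for Langerhans and dendritic cell markers (4.77 to 4.82). ND_cont replicate 4 had 4.90 for hyperproliferation-associated genes (3.43 to 3.64), ND_cont replicate 1 had 3.49 for IL-1 family genes (2.89 to 2.98), ND_cont replicate 2 had 7.39 for cholesterol synthesis (7.21 to 7.23) and ND_cont replicate 3 had 2.45 for matrix proteases (2.96 to 3.04). HFD_cont replicate 1 had 7.40 for skeletal muscle markers (8.47 to 8.52).

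Single genes that stood apart are given in CPM. For Ankk1, Cxcl5, F10, Krt34, Lyg2, Mmp13, Sprr2f, Stfa1 and Uox the other libraries of the group held 0 CPM. The same held for Saa3 in untreated ears, so for these genes a few counts can set a library apart. ND_cont replicate 4 had 110 for Krt6b (2.08 to 3.94 in the others), 170 for Krt6a, 1.68 for Cxcl5, 3.93 for S100a9, 0.337 for Stfa1, 0.449 for Saa3, 0.112 for Lyg2 and 8.64 for Tmem35. ND_cont replicate 1 had 0.370 for Ankk1 and 23.1 for Nfkbiz, replicate 2 had 0.0946 for Sprr2f and 0.189 for Uox, and replicate 3 had 0.0961 for Krt34 and 17.5 for Serpina3b. HFD_cont replicate 1 had 1.73 for Acod1, 49.3 for Comp, 261 for Fabp5, 3.21 for Mmp13, 360 for Myh4, 0.618 for Saa3 and 24.8 for Sprr2h. HFD_cont replicate 2 had 16.4 for Ccr2, 0.232 for F10, 12.6 for Opcml and 202 for Per3, and replicate 4 had 0 for Clec4e, 1.30 for Clec7a and 0.217 for Csf3r. ND_PMA replicate 2 had 21.7 for Ccnb2, 167 for Cers3, 0.322 for Krt34, 2.19 for Robo2, 13.7 for Saa3 and 54.7 for Sprr2h. ND_PMA replicate 1 had 890 for Krt6a, replicate 3 had 1.01 for Lyg2, and replicate 4 had 21.6 for C7, 76.3 for Lgr6 and 298 for Sprr1a. HFD_PMA replicate 1 had 97.1 for Acadl and 47.0 for Krt32 (5.01 to 6.02 in the others), replicate 3 had 53.2 for Cd209a, and replicate 4 had 282 for Junb.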

How the results depend on the processing

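The tests with the hair list mean as a covariate, with the 4 libraries highest in hair genes left out, with HFD_PMA replicate 1 and ND_PMA replicate 2 left out, and of lists with the replicate block were chosen only after the results were seen, and all others were planned. Of 5092 recomputed gene results 4391 kept direction and side of the threshold, 696 lost the call, 3 gained it and 2 reversed. The reversals were Pdk4 in untreated skin, at log2 fold changes of -0.126 with the series covariate and -0.102 among RHS libraries. The diet effect in PMA-treated skin counted 387 genes, against 850 by DESeq2, 155 in a fit of the 8 libraries, 100 without the hair-rich libraries, 194 without HFD_PMA replicate 1 and ND_PMA replicate 2, and 157 (without HFD_PMA replicate 2) to 332 with 1 library left out. The diet effect in untreated skin counted 691, against 1149 by DESeq2, 179 with the series covariate, 131 among RHS libraries, 22 without the hair-rich libraries (each with 1 HFD_cont library left), and 332 (without ND_cont replicate 4) to 653 with 1 left out. The PMA effect counted 2279 in ND mice, against 453 with the series covariate and 1805 to 2173 with 1 left out, and 2101 in HFD mice, against 160 without the hair-rich libraries and 1283 (without HFD_PMA replicate 2) to 2152 with 1 left out. The interaction counted 1, against 22 by DESeq2, 2 without or with a stricter low-count filter, 2 with the replicate block, 2 with the series covariate, 0 without the hair-rich libraries, and 1 to 4 (without ND_cont replicate 2) with 1 left out. Leaving out libraries leaves fewer samples, and without the hair-rich ones HFD_cont replicate 3 stands alone in its group. Otherwise the cause was not tested.

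Lists past the threshold numbered 17, 15, 18, 22 and 7 for the diet in PMA-treated and untreated skin, PMA in ND and HFD mice, and the interaction. With an estimated correlation they were 2, 4, 1, 2 and 0, and with fry 9, 8, 15, 19 and 0. With the series covariate they were 17, 16, 18, 21 and 9, and 17, 13, 15, 21 and 4 of the main lists passed in the same direction. With the hair covariate they were 15, 16, 18, 22 and 11, and 12, 12, 18, 20 and 7 of the main lists did so. Reversed lists had BH-adjusted camera p of 0.996 (hair, diet in PMA-treated skin), 0.86 (clock, diet in untreated skin) and 0.0367 (blood, diet in untreated skin) with the hair covariate, and of 0.889 (immediate early, diet in untreated skin), 0.0496 (immediate early, interaction) and 0.00767 (skeletal muscle, interaction) with the series covariate, and the cause was not tested.

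Replicate numbers paired the libraries weakly if at all. The 24 same-number pairs had correlations of deviations from -0.067 to 0.20, 2 above 0.1 (median 0.013, and 0.00045 for other numbers). Of 16 libraries 8 correlated best with their own number, more than the share of same-number partners alone would give, so some pairing by number stays open. With the number as a block the counts were 358, 669, 2192, 1967 and 2. Scaling to ERCC was not run. Depth limits genes under about 1 CPM.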

Other observations

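The count of calls shared between comparisons was chosen only after the results were seen, and the other tests of this part were fixed before. Some gene groups moved outside the themes above. Of 15 clock genes 2 were lower in untreated HFD skin, Cry2 (264 ± 40.3 to 172 ± 15.3 CPM) and Nr1d1 (383 ± 70.2 to 253 ± 16.7 CPM). Adjusted over the list alone 3 were lower, and camera gave BH-adjusted p = 0.00894 (adjusted p = 0.349 with an estimated correlation). Cry2 lost its call without ND_cont replicate 4 (edgeR BH-adjusted p = 0.0502), and Nr1d1 without ND_cont replicate 3 (adjusted p = 0.0594) or HFD_cont replicate 2 (adjusted p = 0.0549). Krt79, a keratin of the follicle funnel and sebaceous duct, rose there from 582 ± 160.5 to 1198 ± 94.3 CPM. The mitotic genes Ube2c (3.24 ± 1.10 to 8.60 ± 2.04 CPM) and Birc5 (6.27 ± 2.24 to 13.0 ± 4.61 CPM) were the called members of 22 cell cycle genes in untreated skin, and 6 were higher when adjusted over the list alone. For the list camera gave BH-adjusted p = 2.22e-05, and adjusted p = 0.349 with an estimated correlation. Ube2c lost its call without ND_cont replicate 4 (edgeR BH-adjusted p = 0.0706) or HFD_cont replicate 3 (adjusted p = 0.0592). Birc5 lost its call without ND_cont replicate 1, 2 or 3 (edgeR BH-adjusted p = 0.0848, 0.0686 and 0.134) or HFD_cont replicate 1 or 3 (adjusted p = 0.129 and 0.104). In ND mice PMA raised the AP-1 gene Junb from 195 ± 22.0 to 346 ± 63.8 CPM and lowered Fosb from 22.3 ± 19.3 to 3.32 ± 2.80 CPM. Of 16 immediate early and AP-1 genes 2 were higher and 1 was lower, also when adjusted over the list alone, and the list did not pass camera (BH-adjusted p = 0.403). With the diet 1 of the 16 was called, as higher, in PMA-treated and in untreated skin. Camera gave the list as higher there, with BH-adjusted p = 0.019 in PMA-treated and 0.00261 in untreated skin. With an estimated correlation these camera BH-adjusted p were 0.485 and 0.432. Fosb lost its call without ND_cont replicate 1 or 3 (edgeR BH-adjusted p = 0.137 and 0.0832) or ND_PMA replicate 1, 3 or 4 (adjusted p = 0.11, 0.121 and 0.0876). The 13 measured T cell genes as a list passed camera in neither diet with PMA (BH-adjusted p = 0.161 in ND and 0.629 in HFD mice), while fry found it lower in ND mice (BH-adjusted p = 0.0088).

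In HFD mice PMA lowered 2 of 17 cholesterol synthesis genes, among them Dhcr7 (336 ± 26.3 to 252 ± 26.7 CPM), and 5 when adjusted over the list alone. For the list camera gave BH-adjusted p = 0.00292, and adjusted p = 0.335 with an estimated correlation. Dhcr7 lost its call without HFD_cont replicate 3 or 4 (edgeR BH-adjusted p = 0.102 and 0.0864) or HFD_PMA replicate 1 or 2 (adjusted p = 0.0748 and 0.123). The follicle stem cell genes Krt15 (3229 ± 533 to 1110 ± 423 CPM) and Lgr6 (97.2 ± 10.7 to 46.0 ± 17.4 CPM) fell with PMA in HFD mice. Of 12 list members 3 were called lower, and adjusted over the list alone 1 was higher and 5 were lower (camera BH-adjusted p = 0.00397, adjusted p = 0.109 with an estimated correlation). Several cytokine genes that are often assayed in inflamed skin had too few counts to be tested, among them Il6, Il17a, Il17f, Il22, Il23a, Il4, Il5, Il13, Csf2 and Csf3, so no difference was detectable at this depth.

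The diet effects in untreated and PMA-treated skin share no library, and 111 genes were higher in both (4.76 for independent lists), 70 lower in both (2.34 for independent lists) and 0 opposite. Across genes, which are not independent replicates, their log2 fold changes correlated with r = 0.467, and those of PMA in the 2 diets with r = 0.543. Since each gene's dispersion was estimated over all 16 libraries, calls of 2 comparisons are not independent. The numbers for independent lists are only a rough guide.

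Other splits of the same libraries were counted. The real split alone gave as many called genes in 1 of 35 splits for each of the 4 comparisons of 2 groups. The counts were 387, 691, 2279 and 2101 genes against at most 4, 2, 5 and 23 in the other splits, for the diet in PMA-treated skin, the diet in untreated skin, PMA in ND and PMA in HFD mice. A share of 1 in 35 is the smallest these splits can give. For the interaction 3 of 100 splits gave at least the 1 gene of the real one, the highest other giving 2. These splits exchanged diet labels within a treatment, which removes the diet effects along with the interaction, so they do not test the interaction alone.

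Xist had 1, 5, 8 and 2 counts in ND_cont replicates 1 to 4 and 0 in the other 12 libraries, and the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had counts in all 16.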
